A study of Mus musculus with 8 samples.

How the data were processed

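RNA sequencing libraries of interscapular brown fat from 8 mice were analysed, 4 per genotype. The groups were taken from the sample titles, which name each mouse by its genotype and number. Per the labels' protocols, RNA was extracted with a column kit and made into stranded mRNA libraries with unique dual indexes. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2, SAMtools and featureCounts from Subread were used with the mouse genome build GRCm38. Their order, settings and versions, the strand setting of the counting and the annotation release are not given in the sources used here. The deposited values are whole-number read counts per gene, with Ensembl gene IDs and no normalization, and the 8 columns were matched to the samples by the genotype and number in their names. The labels call the 8 samples separate mice.

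The libraries held 12226608 to 19268945 counts each, and 30166 of the 54532 genes had no count in any library. The 20 most abundant genes took 25.4 to 31.1% of the counts and mitochondrial genes 18.0 to 23.8%. No pair of libraries agreed within sampling noise (chi-square per degree of freedom from 10.4 to 79.0 over genes with at least 20 counts), so each counts as 1 replicate. A biological coefficient of variation of 16.4% was estimated. Reads without molecular identifiers are not independent molecules, so limits from a count of 0 (3 counts of the total) cover counting error only. Gene positions and overlaps came from GENCODE mouse release 21, on the same build, which held 54409 of the 54532 IDs (99.8%). It may not be the release used for counting.

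From the deposited counts, CPM were computed with TMM-scaled library sizes. Genes were filtered with filterByExpr, which left 13756, and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on an intercept and the genotype, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p for genes are from this test unless another tool is named. Each SE is the absolute log2 fold change divided by the square root of the test's F. The 30 gene lists, the naming rule and the design were fixed before the data were examined. Lists with at least 5 measured members (29) were tested with camera at its preset inter-gene correlation of 0.01 and adjusted over the 29. Camera with an estimated correlation and fry stand beside it. No list passed with an estimated correlation, and 1 was under an unadjusted p of 0.05. List scores are mean log2 CPM with a prior count of 2 and were compared by exact permutation tests. No list passed these tests adjusted over the 30 lists, with a lowest adjusted p of 0.171. The named genes are Pparg and Myl1, 9 fixed markers, the 10 largest and the 10 smallest log2 fold changes among genes past the threshold with a mean CPM of at least 1 and no overlap between the groups (predicted genes without a name skipped), and for each list up to 4 passing members by p or, where none passed, the 2 most abundant. A gene that this rule names is not reported here. Members named as passing over a list alone, and Mif, fall outside the rule and were chosen after their values were seen.

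On simulated counts for this comparison (13583 genes tested) the same test recovered 31.8% of genes changed 1.5-fold, 71.2% of those changed 2-fold and 95.4% of those changed 4-fold, with 6.47% of calls false. The list test recovered the changed list (adjusted p = 6.85e-11) and called 0 of 29 other lists. The simulated genes were drawn independently and the lists at random. This check therefore cannot show false list calls among genes that vary together, and its gene rates leave out such shared variation. In the real libraries the estimated inter-gene correlation was 0.21 for the PPARG target list and 0.79 for the skeletal muscle list.

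The alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings, no filter and a stricter filter on low counts, robust dispersion, the mouse number as a block, the 20 most abundant genes left out, the muscle score as a covariate, other thresholds, and each library left out in turn. Outliers within a group of 4 were found with Dixon's ratio (above 0.829). All 35 splits of the 8 libraries into 4 and 4 were fitted.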

Results

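RNA was measured in the interscapular brown fat of 8 mice, a fat depot that burns lipid to make heat. The mice were 7-month-old males held at 4 °C for 24 h. By the labels, 4 of them carried a floxed Pparg gene together with Myl1-Cre, a recombinase expressed where the myosin light chain gene Myl1 is active, and 4 carried the floxed gene alone and serve as the control. Pparg encodes the nuclear receptor that drives fat cell formation, and the series asks what fat cells formed from Myl1-positive progenitor cells contribute to brown fat. The deposited table gives a read count for 54532 genes in each library. The control libraries 1 to 4 held 14017665, 19268945, 12679589 and 12407466 counts, and the libraries labelled knockout 1 to 4 held 12226608, 14377951, 15814937 and 16977010. A count of 0 in 1 library therefore allowed a level of up to 0.156 to 0.245 CPM (counts scaled by library size), which covers counting error only. After the filter on low counts 13756 genes were tested. Levels are mean CPM ± SD over 4 mice per group, and log2 fold changes are the libraries labelled knockout over the control, with their standard error (SE).

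The targeted gene was examined first. Pparg (ENSMUSG00000000440, GRCm38 chromosome 6, 115360951 to 115490399, plus strand) had more RNA in the libraries labelled knockout, at 284 ± 24.9 CPM against 197 ± 7.36 CPM in the control, a log2 fold change of 0.52 ± 0.09 (SE) with an adjusted p of 0.0328, and each of the 4 lay above each control. This direction goes against the label, so the group is called the libraries labelled knockout throughout, and every direction below is drawn from the labels as given. A gene-level count includes exons outside the floxed part, and Cre acts in a part of the cells of the tissue, so the count checks the label only in a limited way. Leaving out any 1 of the 8 libraries ended the call, with adjusted p between 0.0505 and 0.119 and log2 fold changes between 0.46 and 0.55. These p are adjusted over all genes although Pparg was named in advance, and its unadjusted edgeR p with all 8 libraries was 0.000103. Myl1 (ENSMUSG00000061816, chromosome 1, 66924295 to 66945404, minus strand) was at 367 ± 105 CPM in the libraries labelled knockout and 378 ± 68.8 CPM in the control, with a log2 fold change of -0.05 ± 0.20 (SE) and an adjusted p of 0.94.

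Skeletal muscle lies next to interscapular brown fat, and the mean log2 CPM of 32 skeletal muscle genes was taken as a score of its content. The score cannot separate carried-over muscle from muscle transcripts that differ with the labelled genotype. A call lost with the score as a covariate therefore does not by itself show carried-over muscle as the cause. This score was 8.75 ± 0.44 (SD, n = 4) in the libraries labelled knockout and 8.05 ± 0.56 (SD, n = 4) in the control, a difference of 0.70 or a ratio of 1.62, with an exact two-sided permutation p of 0.0857. The smallest p that 4 against 4 libraries can give is 0.0286. Control 1 had the lowest score, at 7.29, and labelled knockout 4 lay near the control libraries, at 8.10 against 8.90 to 9.02 in the other libraries of its group.

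**Figure D1:**
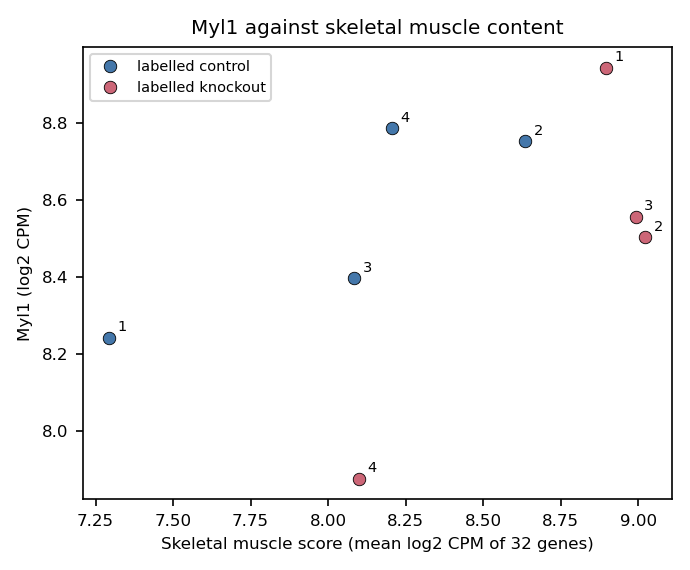
Log2 CPM of Myl1 in each library (vertical axis) against its skeletal muscle score, the mean log2 CPM of 32 genes (horizontal axis), with points numbered by mouse and coloured by group. The score runs from 7.29 in control 1 to 9.02 in labelled knockout 2, and the mean Myl1 level is 378 CPM in the control and 367 CPM in the libraries labelled knockout.

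Between the groups 53 genes passed an adjusted p of 0.05, 40 of them higher and 13 lower in the libraries labelled knockout. Among the higher genes with counts in the control, changes ran from a 122-fold rise of the sulfotransferase gene Sult1e1 down to a log2 fold change of 0.47 for the cytokine gene Mif, whose call was lost without any 1 library, and the lower genes with a gene name spanned -1.14 for Klb to -0.54 for Slc25a42. In all 53 the 4 libraries of one group lay apart from the 4 of the other, which selection by a small p nearly ensures. Such separation occurred in 8.10% of all tested genes, where chance alone gives 2.86% per gene. Genes that move together can shift this share, and it was not computed for other splits, so it does not show an effect of the genotype. The count depended on the test and filter, with 209 higher and 152 lower genes in DESeq2, 118 and 69 with no filter on low counts, and 25 and 2 with the skeletal muscle score as a covariate, which kept 26 of the 53. It fell to 25 higher and 3 lower genes without control 2, 23 and 1 without labelled knockout 1 and 26 and 0 without labelled knockout 3 (1585 genes at an unadjusted p under 0.05 in that edgeR fit), while the lower genes numbered 5 without control 1, 3 without control 4, 7 without labelled knockout 4 and 37 without control 3.

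**Figure D2:**
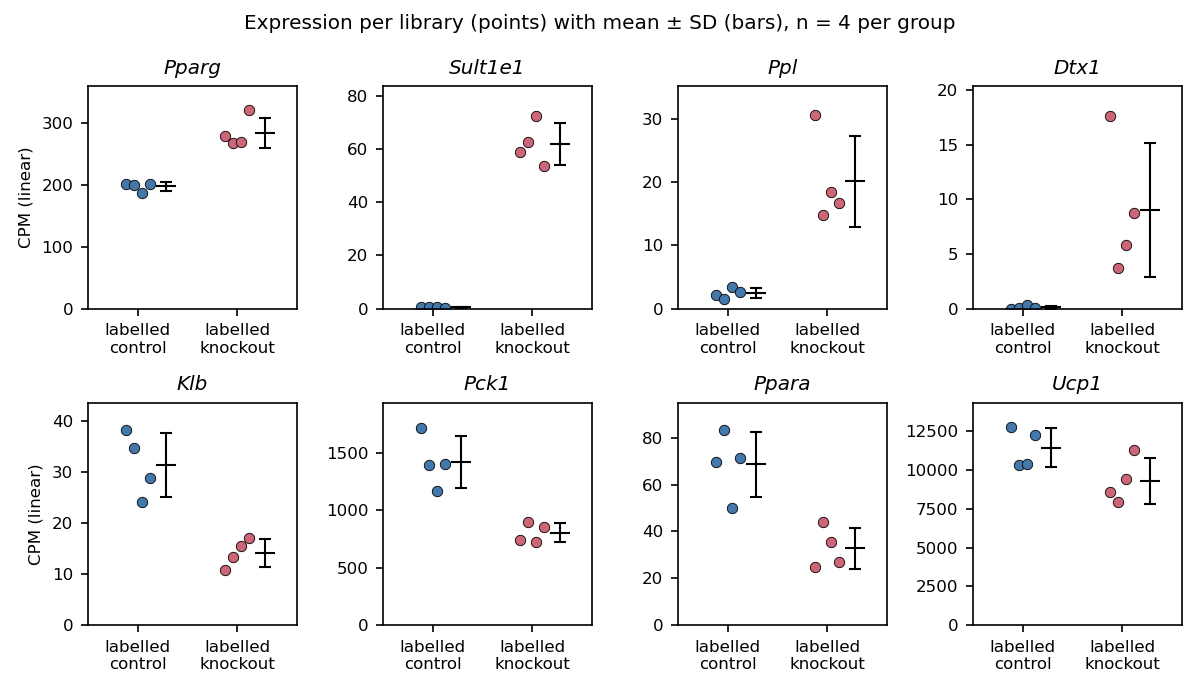
CPM of 8 genes in each library (points) with the mean ± SD beside them (bars, n = 4), for the control and the libraries labelled knockout, on linear axes that start at 0. Pparg, Sult1e1, Ppl and Dtx1 lay higher and Klb, Pck1 and Ppara lower in all 4 libraries labelled knockout, while the groups overlapped for Ucp1, at 11441 ± 1272 and 9303 ± 1473 CPM.

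The largest rises were of genes that were near silent in the control. Sult1e1 (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594), which encodes the enzyme that sulfates and inactivates oestrogens, rose from 0.481 ± 0.193 to 61.9 ± 7.92 CPM (log2 fold change 6.93 ± 0.20, adjusted p = 1.29e-08). Lrrc75b (chromosome 10, 75550123 to 75560330) had 0 counts in the 4 control libraries and 4.42 ± 1.08 CPM in the libraries labelled knockout, which is at least 84.0-fold higher against a floor of 3 counts over the control group. Dtx1 (chromosome 5, 120680202 to 120711927), a regulator of Notch signalling, rose from 0.113 ± 0.141 to 8.97 ± 6.13 CPM, and Saa3 (chromosome 7, 46711998 to 46715700), an acute-phase serum amyloid gene, from 0.23 ± 0.284 to 10.5 ± 5.86 CPM. Both varied widely among the libraries labelled knockout. The plakin gene Ppl (chromosome 16, 5086291 to 5132421) rose from 2.42 ± 0.78 to 20.1 ± 7.11 CPM with an adjusted p of 0.00154, and the matrix gene Adamtsl2 from 1.24 ± 0.441 to 11.9 ± 4.17 CPM.

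The remaining rises by the naming rule were of Clic6, an intracellular chloride channel gene, from 0.0637 ± 0.0439 to 2.05 ± 0.856 CPM, S100g, a vitamin D-regulated calcium-binding protein gene, from 0.111 ± 0.0883 to 1.96 ± 0.412 CPM, Mup3 from 0.281 ± 0.316 to 4.98 ± 1.08 CPM and Lcn2, which encodes the secreted iron-scavenging protein lipocalin 2, from 0.561 ± 0.494 to 6.12 ± 2.69 CPM. Mup3 belongs to the major urinary protein family, whose near-identical copies share reads, so its value is uncertain. Summed over the 4 control libraries Clic6 had 4 counts, Dtx1 6, S100g 7, Saa3 13 and Mup3 15, so the base of each fold rests on few counts. Without control 3 the log2 fold changes of Dtx1 and Saa3 went from 6.30 to 7.41 and from 5.49 to 6.48, and without control 1 that of Mup3 from 4.19 to 5.10. With the muscle score as a covariate that of Saa3 fell from 5.49 to 4.09 and that of Adamtsl2 from 3.30 to 2.70. Of these 10 genes, 9 stayed past the threshold whichever library was left out and with the muscle score as a covariate. Lcn2 (adjusted p = 0.0221) passed in 4 of those 8 fits, losing its call without control 1 or 2 or labelled knockout 2 or 3, and had an adjusted p of 0.147 with the covariate, while Saa3 and Lcn2 missed the threshold with limma-voom, both at an adjusted p of 0.088.

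The 10 lower genes taken by the naming rule had control levels between 21.7 CPM for Rnf24 and 1419 CPM for Pck1. Klb (ENSMUSG00000029195, chromosome 5, 65348314 to 65384007), the co-receptor that lets cells respond to FGF21, fell from 31.5 ± 6.3 to 14.2 ± 2.75 CPM, a log2 fold change of -1.14 ± 0.17 with an adjusted p of 0.0163. Ppara (chromosome 15, 85734983 to 85802819), a nuclear receptor for fatty acid oxidation genes, fell from 68.6 ± 13.8 to 32.8 ± 8.75 CPM (log2 fold change -1.07 ± 0.19, adjusted p = 0.0441). Pck1 (chromosome 2, 173153048 to 173159273), whose enzyme supplies the glycerol backbone of triglycerides in fat cells, fell from 1419 ± 225 to 803 ± 83.0 CPM, with a log2 fold change of -0.82 ± 0.13. Lipa, the lysosomal acid lipase gene, fell from 209 ± 26.3 to 131 ± 8.46 CPM, Prkag2, a regulatory subunit of the energy sensor AMPK, from 94.6 ± 4.71 to 61.5 ± 8.67 CPM, and Slc25a42, a mitochondrial coenzyme A transporter, from 374 ± 19.3 to 256 ± 11.1 CPM. The other falls in this group were of Rnf24 (log2 fold change -0.78), Ctcflos (-0.73), Gtf2ird1 (-0.62) and Sowahc (-0.56). Exons of Ctcflos, Rnf24, Prkag2 and Gtf2ird1 overlap those of a gene on the opposite strand, and the strand setting of the counting is not given in the sources used here, so their values are uncertain.

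None of these 10 lower genes stayed past the threshold without labelled knockout 3, and Ctcflos alone did without labelled knockout 1. Their log2 fold changes without labelled knockout 3 lay between -1.19 for Klb and -0.55 for Sowahc. In the main fit these 2 genes were at -1.14 and -0.56. A fit that leaves out 1 library also has fewer samples. Ctcflos passed in 7 of the 8 fits that left out 1 library, Rnf24 in 6, Klb in 5, Lipa in 3 and each of the other 6 in 2, with adjusted p up to 0.164. With the muscle score as a covariate, Slc25a42 passed and the other 9 did not, with adjusted p from 0.057 to 0.285, and their log2 fold changes then lay between -1.26 for Ppara and -0.46 for Sowahc. Ppara also missed the threshold with total count scaling and with robust dispersion, and Gtf2ird1 with upper-quartile scaling.

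Heat production by brown fat rests on Ucp1, the uncoupling protein of its mitochondria, and 9 marker genes of brown or general fat cells are given whether or not they passed. Ucp1 (chromosome 8, 83290352 to 83298452) was at 9303 ± 1473 CPM in the libraries labelled knockout and 11441 ± 1272 CPM in the control, a log2 fold change of -0.30 ± 0.14 with an adjusted p of 0.344. Elovl3, a fatty acid elongase induced by cold, stood at 680 ± 139 against 1311 ± 463 CPM, with a log2 fold change of -0.95 ± 0.24 and an adjusted p of 0.125. It lay lower in all 4 libraries, and it passed in DESeq2 (adjusted p = 0.00518) and in edgeR with no filter on low counts (0.017). The log2 fold changes of the others were -0.51 ± 0.26 for Ppargc1a, -0.45 ± 0.20 for Dio2, -0.38 ± 0.19 for Prdm16, -0.25 ± 0.12 for Adipoq, -0.24 ± 0.13 for Fabp4, -0.19 ± 0.11 for Cidea and 0.40 ± 0.29 for Lep, and none passed, with adjusted p from 0.311 to 0.535. These values are adjusted over all genes tested, although the 9 markers were named in advance. The unadjusted edgeR p was 0.00198 for Elovl3, 0.0422 for Dio2 and from 0.0584 for Ucp1 to 0.191 for Lep among the rest. Exons of Elovl3, Dio2 and Prdm16 overlap those of a gene on the opposite strand, so their values are uncertain.

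Target genes of PPARG lay lower as a group in the libraries labelled knockout, although Pparg RNA itself was higher. Of 39 measured targets 36 had a log2 fold change below 0, with a median of -0.25, and the list fell relative to the other genes (camera adjusted p = 5.45e-09 with the preset correlation). Pck1 passed over all genes tested. Adjusted over the list alone, 10 were lower, among them Plin1, Lipe, Cebpa and Gpd1, and 1 was higher. With an estimated correlation the adjusted p was 0.427, so this call rests on the preset value. The mean log2 CPM of the list was 9.20 ± 0.111 in the libraries labelled knockout and 9.47 ± 0.0862 in the control (exact two-sided permutation p = 0.0286, adjusted p = 0.171 over 30 lists). As 0.0286 is the smallest p this test can give, the adjusted value could pass only if many lists tied at it. The list also passed camera with the muscle score as a covariate.

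Other lists of fat cell metabolism went the same way. The thermogenic and brown adipocyte list (36 measured) had a median of -0.30 and a camera adjusted p of 1.52e-05, with Ppara the 1 member past the threshold, and 11 lower and 1 higher adjusted over the list alone. Among 35 fatty acid oxidation genes 29 lay below 0, with a median of -0.24 and an adjusted p of 1.43e-05. No member passed over all genes, and adjusted over the list alone 1 passed, Cpt1a, which was higher, against the direction of the list. Acsl1 had a log2 fold change of -0.41 ± 0.13 and Acadvl -0.21 ± 0.10. Both values are uncertain for the same overlap as that of Elovl3. Lipid droplet and lipolysis genes (23 measured) had a median of -0.24 and an adjusted p of 3.1e-05, with Lipa past the threshold and 8 lower and 2 higher adjusted over the list alone. Fatty acid and triglyceride synthesis genes (26 measured) had a median of -0.25 and an adjusted p of 0.000625 with no member past the threshold. Scd1 stood at 4240 ± 1230 against 8407 ± 4964 CPM and Fasn at 5313 ± 3085 against 8202 ± 3136 CPM. With an estimated correlation the adjusted p was 0.427 for the first 3 of these lists and 0.451 for the synthesis list. With the skeletal muscle score as a covariate the thermogenic list missed the threshold (adjusted p = 0.112) and the median of the synthesis list turned to 0.03. The synthesis list also missed it without labelled knockout 2, at an adjusted p of 0.0588 and a median of -0.15. Its median was -0.16 without control 1 and -0.41 without labelled knockout 4. Without labelled knockout 1 the medians of the oxidation and lipolysis lists were both -0.15.

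Muscle transcripts moved in the other direction. All 32 skeletal muscle genes lay above 0, with a median log2 fold change of 0.68 and a camera adjusted p of 4.57e-14, and 0 of them passed alone (edgeR, 20 higher at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom). Myh4, a fast myosin, was at 3313 ± 908 against 1792 ± 827 CPM, and Acta1, skeletal actin, at 2327 ± 602 against 1481 ± 543 CPM. The creatine and calcium cycling list (13 measured), which shares Atp2a1 and Ryr1 with the muscle list, had a median of 0.44 and an adjusted p of 0.0171. Its most abundant members were Atp2a1, at 2152 ± 484 against 1265 ± 592 CPM, and Atp2a2, with a log2 fold change of 0.35 ± 0.20. Exons of both overlap those of a gene on the opposite strand. For both lists the adjusted p was 0.427 with an estimated correlation. With the muscle score as a covariate the creatine and calcium median became -0.04, and the list missed the threshold without control 1 (adjusted p = 0.0604) or labelled knockout 2 (0.0675).

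**Figure D3:**
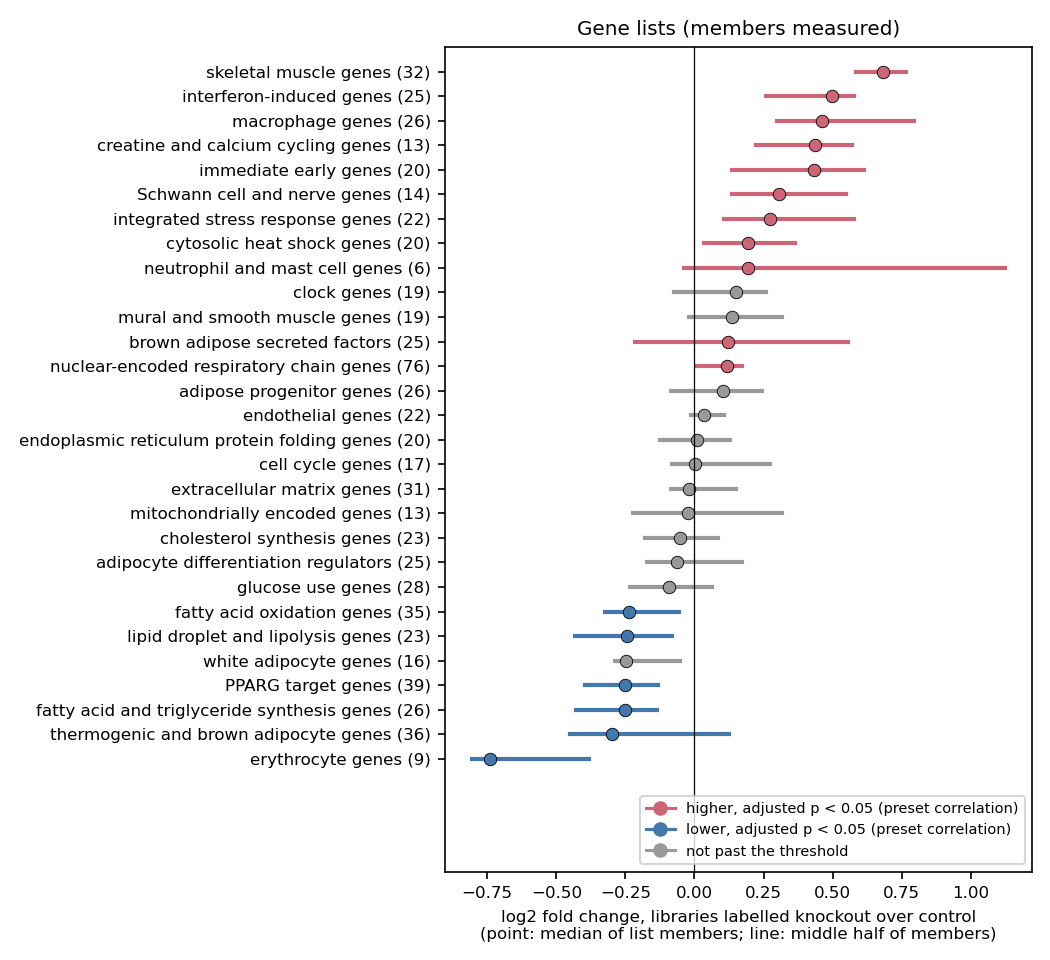
Median log2 fold change of each of the 29 tested gene lists, libraries labelled knockout over control (points), with the middle of each list's members from the first to the third quartile (lines) and the number of members measured in brackets. Lists of fat cell metabolism and of erythrocytes, with medians from -0.74 to -0.24, lay lower, and the skeletal muscle list, with a median of 0.68, lay highest.

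Lists of immune and interferon genes lay higher. The macrophage list (26 measured) had 24 members above 0, a median of 0.46 and a camera adjusted p of 4.17e-06. No member passed over all genes, and Cd68, Lgals3 and Mpeg1 did adjusted over the list alone. Lgals3 stood at 21.7 ± 10.2 against 11.5 ± 0.755 CPM and passed in DESeq2 (adjusted p = 0.0308) and with no filter on low counts. Interferon-induced genes (25 measured) had a median of 0.50 and an adjusted p of 1.43e-05, none of them past the threshold, and the abundant member Ifi27 had a log2 fold change of 0.05 ± 0.10. The interferon median was 0.30 without control 1, 0.31 without labelled knockout 1 and 0.20 with the muscle score as a covariate. The neutrophil and mast cell list had 6 measured members, a median of 0.19 and an adjusted p of 0.0483, with Lcn2, which fat cells also make, the 1 past the threshold and 3 members below 0. For these 3 lists the adjusted p was 0.427 with an estimated correlation. With the muscle score as a covariate the macrophage list missed the threshold, at an adjusted p of 0.256 and a median of 0.09. The neutrophil list missed the threshold in 5 of the 8 fits that left out 1 library (control 2 or 4, labelled knockout 1, 2 or 4), and its median was then between -0.24 and 0.38, while it was 0.10, 0.41 and 0.33 without control 1, control 3 or labelled knockout 3. It also missed it with upper-quartile scaling (adjusted p = 0.055), total count scaling (0.0728), limma-voom (0.25) and no filter (0.377, where its median was -0.21). Of 26 lymphocyte genes only Jchain was measured, at 13.5 ± 3.31 against 9.04 ± 3.42 CPM, so that list was not tested.

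Lists of immediate early, cytosolic heat shock and integrated stress response genes lay higher too. The endoplasmic reticulum protein folding list did not pass (median 0.01, camera adjusted p = 0.875). Immediate early genes (20 measured), which are switched on within minutes of a stimulus, had a median of 0.43 and a camera adjusted p of 1.43e-05. Fosl2, Jun and Ier5 passed adjusted over the list alone and none over all genes, while Jund and Dusp1, the most abundant, had log2 fold changes of 0.18 ± 0.14 and 0.02 ± 0.16. Exons of both overlap those of a gene on the opposite strand. The adjusted p of this list was 0.152 with an estimated correlation, the lowest of the 29 lists, and it was the 1 list to pass fry's directional test, at 0.0356. Cytosolic heat shock genes (20 measured) had a median of 0.20 and an adjusted p of 0.000157, with Hsph1, Hspb1, Hspa1a, Bag3 and Hspa1b higher adjusted over the list alone and none over all genes. Hspa1a and Hspa1b are near-identical and share reads. Hspa8 was at 1435 ± 111 against 1134 ± 216 CPM, and Hsp90ab1 had a log2 fold change of 0.04 ± 0.11. Integrated stress response genes (22 measured) had a median of 0.27 and an adjusted p of 0.00193. Nupr1, a stress-induced chromatin protein gene, rose from 15.6 ± 2.85 to 27.9 ± 2.70 CPM (adjusted p = 0.0221, kept in 2 of the 8 fits that left out 1 library, those without control 3 or labelled knockout 2, and lost with the muscle score as a covariate, at 0.143). With that covariate the Nupr1 log2 fold change was 0.81, against 0.84 in the main fit. With an estimated correlation the adjusted p was 0.427 for the heat shock and stress response lists. With the muscle score as a covariate the heat shock median was 0.12. The stress response list had an adjusted p of 0.392 and a median of -0.03 with the muscle score as a covariate, and an adjusted p of 0.0588 and a median of 0.18 without labelled knockout 2. Its median was 0.46 without control 2 and 0.48 without labelled knockout 4.

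Among lists of other cells and products, Schwann cell and nerve genes (14 measured) had a median of 0.30 and a camera adjusted p of 0.00774. Pmp22, a myelin protein gene that connective tissue cells also express, rose from 36.6 ± 2.69 to 51.8 ± 3.83 CPM (adjusted p = 0.0416), a call that leaving out any 1 library ended, with adjusted p up to 0.148, as did the muscle score as a covariate, at 0.0592. With that covariate the Pmp22 log2 fold change was 0.59, against 0.50 in the main fit. The list missed the threshold without labelled knockout 4, at 0.0611, and its median was 0.17 without labelled knockout 1. Brown adipose secreted factors (25 measured) had a median of 0.12 and an adjusted p of 0.0483, with Lcn2 and the chemokine gene Cxcl14 past the threshold and 5 higher and 2 lower adjusted over the list alone. Cxcl14 rose from 36.2 ± 5.95 to 87.6 ± 20.9 CPM, with a log2 fold change of 1.27 ± 0.17 and an adjusted p of 0.00824, and kept its call in each fit that left out 1 library. The list itself missed the threshold without control 4 (adjusted p = 0.171) or labelled knockout 4 (0.328), and with upper-quartile scaling (0.055), total count scaling (0.0728) or limma-voom (0.148). Its median was 0.20 without control 1 or labelled knockout 1, 0.07 without labelled knockout 2 and 0.04 with the muscle score as a covariate. Nuclear-encoded respiratory chain genes (76 measured) had a median of 0.12 and an adjusted p of 0.00354, with none past the threshold, and missed it without control 2 (adjusted p = 0.121, median 0.08) or labelled knockout 4 (0.209, median 0.07), while with the muscle score as a covariate the median was 0.22. Atp5b and Atp5a1, the most abundant, had log2 fold changes of -0.12 ± 0.10 and -0.07 ± 0.10. Exons of Atp5a1 overlap a gene on the opposite strand. Erythrocyte genes (9 measured) had a median of -0.74 and an adjusted p of 0.000183, with none past the threshold, and without labelled knockout 1 the median was -1.25 and the log2 fold change of Hbb-bs -1.27. Hbb-bs stood at 378 ± 239 against 631 ± 208 CPM and Hba-a1, which shares reads with its near-identical copy, at 211 ± 132 against 347 ± 117 CPM. With an estimated correlation the adjusted p was 0.705 for the respiratory chain list and 0.427 for the other 3.

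The remaining 12 lists did not pass with all 8 libraries and the main settings. Their median log2 fold changes ran from -0.25 for white adipocyte genes to 0.15 for clock genes, with camera adjusted p from 0.0894 for glucose use genes to 0.929 for mitochondrially encoded genes. Extracellular matrix genes included Lox, which encodes the enzyme that cross-links collagen and rose by a log2 fold change of 0.69 ± 0.11 (adjusted p = 0.0208, kept without control 1 or 3 or labelled knockout 4 and lost in the other 5 fits that left out 1 library and, at 0.145 with a log2 fold change of 0.70, with the muscle score as a covariate), and adipocyte differentiation regulators included Pparg. Exons of Lox overlap those of a gene on the opposite strand, so its value is uncertain. Median and mean of these 2 lists differed in sign, -0.02 against 0.07 and -0.06 against 0.00, and the camera direction of the mitochondrially encoded list and of the endoplasmic reticulum protein folding list differed from the sign of their medians, -0.02 and 0.01. Some of the 12 passed under other settings. Glucose use genes were lower without control 2 (adjusted p = 0.0299), control 3 (0.0117) or labelled knockout 4 (0.0216) and with no filter on low counts (0.0385), and white adipocyte genes without control 1 (0.0244) or control 4 (0.0135), with no filter (0.0378) and with the muscle score as a covariate (0.0292). Adipose progenitor genes were higher without control 2 (0.0365) and with no filter (0.0456), and endothelial genes without control 3 (0.0335). Cholesterol synthesis genes were lower without control 2 (0.0152) and higher with the muscle score as a covariate (0.00378). Apart from Lox and Pparg, no member of the 12 lists passed over all genes in the main fit. Their abundant members had log2 fold changes of -0.04 ± 0.14 for mt-Co1, -0.02 ± 0.16 for mt-Cytb, 0.13 ± 0.15 for Hspa5, -0.08 ± 0.10 for Calr, -0.41 ± 0.13 for Hmgcs1 and -0.49 ± 0.19 for Acat2 of cholesterol synthesis, -0.21 ± 0.21 for Eno1 and 0.13 ± 0.15 for Aldoa of glucose use, and -0.31 ± 0.25 for Cfd and -0.09 ± 0.23 for Car3 of white adipocytes. Cell type and timing lists had 0.18 ± 0.19 for Gsn and -0.17 ± 0.12 for Cxcl12 of adipose progenitors, 0.70 ± 0.23 for Des and 0.02 ± 0.13 for Rgs5 of mural and smooth muscle cells, -0.08 ± 0.14 for Kdr and 0.03 ± 0.11 for Eng of endothelium, 0.33 ± 0.10 for Pcna and -0.00 ± 0.11 for Mcm7 of the cell cycle, and -0.27 ± 0.18 for Nr1d1 and -0.05 ± 0.19 for Tef of the clock. Of these, the values of mt-Co1, Hmgcs1, Aldoa, Des, Eng, Mcm7, Nr1d1 and Tef are uncertain for the same reason as that of Lox.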

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

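The tests of library scaling, of exchanged labels, of tissue markers low in the control, of Myl1 against the muscle score and the other muscle genes and of the splits with that score were chosen only after the result was seen. Within the groups, 13 values lay far from the other 3 libraries of their group, out of 220 groups examined, where chance alone gives about 11. In control 3, Pparg (186 CPM against 200 to 202), Prkag2 (87.5 against 96.4 to 97.2) and Atp5a1 (3063 against 3244 to 3257) were low and Eng (255 against 194 to 200.2) was high. In control 2, Lyz2 (67.4 CPM against 47.7 to 48.0) was high and the erythrocyte score (5.13 against 5.99 to 6.08, mean log2 CPM) was low. In labelled knockout 1, Lipa (119 CPM against 134 to 137) and Acadvl (1785 against 2148 to 2203) were low. In labelled knockout 4, Adamtsl2 (5.71 CPM against 13.4 to 14.5), Atp2a1 (1426 against 2362 to 2424), Des (476 against 766 to 823), the score of adipocyte differentiation regulators (5.02 against 5.09 to 5.11) and the skeletal muscle score (8.10 against 8.90 to 9.02) were low.

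Pparg RNA was higher, not lower, in the libraries labelled knockout. The scaling of the libraries is argued against, since the lowest Pparg log2 fold change over 5 scalings was 0.52. An exchange of the labels of both groups as a whole is argued against by the PPARG target list, whose median log2 fold change was -0.25 and which lay lower in the fit with the muscle score as well. That argument leans on the preset correlation, as the list's adjusted p was 0.427 with an estimated one. What stays open, and was not tested, is that transcripts lacking the floxed part may still be counted over the rest of the gene, or that the gene may be raised in cells that Cre does not reach.

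The 18 genes raised at least 4-fold had a median log2 fold change of 3.37, and all 18 lay apart between the groups, which their selection nearly ensures. The median log2 fold changes of 3 lists of markers of liver, kidney and epithelium, 0.20 at the highest, exclude nothing by themselves, as the 1 kidney marker measured, Aqp1, is at 113 CPM in the control. RNA from liver, kidney or epithelium is argued against by the markers under 10 CPM in the control, 19, 15 and 18 of them, whose summed CPM differed by -1.51 ± 3.02, 0.126 ± 0.397 and 0.902 ± 1.16 (difference ± standard error) against a median rise of 5.13 CPM of the 18 genes, and Kap and Krt14 are listed at 0 in all 8 libraries. This comparison does not cover genes that rose by less than the median, such as Clic6 and S100g, which reached 2.05 and 1.96 CPM. More skeletal muscle is argued against as the whole cause, since with the muscle score as a covariate the median was 3.14 and 14 of the 18 still passed. A response of the tissue to the labelled genotype stays open and was not tested, as these libraries hold no contrast that separates the genotype from what else differs between the 2 groups. Among the 18, Lrrc75b and Gm867 start at 75550123 and 75937723 on chromosome 10, near the called gene Mif at 75859353. Whether this closeness bears on their rises was not tested.

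Myl1 had a log2 fold change of -0.05, while all 32 skeletal muscle genes lay above 0, the lowest of them Myh2 at 0.26. Log2 Myl1 CPM minus the muscle score differed by -0.77, labelled knockout minus control (a ratio of 0.585, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give). Of the 32 muscle list members, 1, Casq1, was also lower in all 4 libraries labelled knockout relative to the others, and 0 had a difference as low as that of Myl1. A candidate explanation is lower Myl1 output per muscle cell in that group, for example where a Cre insertion takes 1 copy of the gene, but the labels do not describe the construct. These values do not tell that explanation apart from ordinary spread between muscle genes. Myl1 lies 0.30 ± 0.51 below Myh2, but this error treats both genes as independent although they come from the same libraries, so it may be too wide. The subtraction in part restates the first sentence. With a fitted muscle slope the Myl1 log2 fold change was -0.46 ± 0.18. Its adjusted p was 0.468 (the other alternatives reached 0.994), adjusted over all genes although Myl1 was named in advance.

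Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least the 53 genes of the real one, the real one included, so chance cannot be excluded by the count. The highest other split gave 257 genes. It exchanges control 2 with labelled knockout 4 and has the largest difference in muscle score of all splits, at 0.966 against 0.698 for the real one. That points to a structure of the samples: 14 of the 32 skeletal muscle genes pass in it, none of its 257 genes is among the 53, and with the muscle score as a covariate it gave 0 genes (edgeR, the 1 tool run on it, with 558 genes at an unadjusted p under 0.05 against 2195 before), which is consistent with skeletal muscle content of the libraries as its source. A covariate that differs so much between the groups of a split also costs calls by itself. With that covariate in every split, 2 of 35 gave at least the 27 genes of the real one, and the highest other gave 80, so chance could not be excluded there either.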

How the results depend on the processing

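The counts of 40 higher and 13 lower genes stayed within 1.5 times under 3 other scalings, a stricter filter, robust dispersion, limma-voom and without the 20 most abundant genes. DESeq2 gave 209 and 152, no filter on low counts 118 and 69, an adjusted p under 0.1 gave 73 and 53, an absolute log2 fold change of at least 1 gave 29 and 5, and the muscle score as a covariate 25 and 2. Leaving out 1 library, which also leaves fewer samples, gave 23 to 38 higher and 0 to 37 lower genes, the 37 without control 3. The cause of the differences in these counts was not tested.

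Whether the mouse numbers pair the samples stays open. The correlations of same-numbered libraries were 0.02, 0.40, 0.03 and 0.17. Numbers 2 and 4 correlated best with themselves, while controls 1 and 3 correlated best with labelled knockouts 4 and 1. With the replicate block 109 genes were higher and 46 lower, 51 of the 53 among them, the glucose use list passed (adjusted p = 0.0368) and the Pmp22 call was lost (0.0523).

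Of the 11 higher and 6 lower lists, 0 and 0 passed with an estimated correlation. Their scores had an unadjusted exact permutation p of 0.0286 for the PPARG target, neutrophil, heat shock, immediate early and secreted factor lists. It was 0.0571 for the oxidation, lipolysis, macrophage and Schwann cell lists. For the thermogenic, creatine, skeletal muscle and erythrocyte lists it was 0.0857. The interferon, respiratory chain, stress response and synthesis lists had 0.114, 0.143, 0.229 and 0.257. The higher lists numbered 7 to 12 when 1 library was left out, 7 without labelled knockout 4. With the muscle score as a covariate the medians of the creatine and calcium cycling list (-0.043), the fatty acid and triglyceride synthesis list (0.032) and the cholesterol synthesis list (0.21, adjusted p = 0.00378, over all alternatives up to 0.954) changed sign together with the direction of their test, and the cause was not tested. The Pparg log2 fold change kept its sign and its call under 11 alternatives, and without 1 library lay between 0.46 and 0.55 with the call lost each time. The muscle score difference stayed between 0.44 and 0.92.

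Of 969 values of the other 89 genes examined, 938 stayed on their side of the threshold, 21 lost it and 10 gained it, and no call changed direction. When 1 library was left out, 628 of 712 stayed, 83 lost the threshold and 1 gained it. Of 318 values of list tests 282 stayed, 28 lost the threshold, 5 gained it and 3 changed direction, and of 232 with 1 library left out 210 stayed, 14 lost it and 8 gained it. No value was obtained for Clic6 and the neutrophil and mast cell list under the stricter filter, nor for 9 named genes that are themselves among the 20 most abundant. Depth limits the genes near silent in the control, where 4 to 15 summed counts set the fold, and with 4 mice per group a 1.5-fold change is recovered in 31.8% of simulated genes.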

Other observations

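These values lie outside the naming rule and were chosen after they were seen. Gpx3, the secreted glutathione peroxidase, was the most abundant of the higher genes, at 1574 ± 209 against 723 ± 36.4 CPM (log2 fold change 1.12 ± 0.11, adjusted p = 0.00189), while the cellular Gpx1 and Gpx4 had log2 fold changes of -0.02 ± 0.10 and 0.01 ± 0.11. Ucp2, a relative of Ucp1 in the inner mitochondrial membrane, rose from 46.3 ± 4.07 to 149 ± 46.0 CPM, with an adjusted p of 0.00255. The metallothionein gene Mt2 rose from 33.0 ± 6.09 to 66.4 ± 7.23 CPM, and Mt1 lay at 207 ± 33.5 against 142 ± 7.10 CPM with an adjusted p of 0.0909. Clu, Pon1 and Vcam1 rose with log2 fold changes of 1.38 ± 0.16, 1.44 ± 0.18 and 1.14 ± 0.19, and Cyp1b1 with 2.29 ± 0.18. Vcam1 lost its call in 5 of the 8 fits that left out 1 library (control 2 or 3, labelled knockout 1, 2 or 3, adjusted p 0.0586 to 0.116) and with the muscle score as a covariate (0.164, log2 fold change 1.13), while Gpx3, Ucp2, Mt2, Clu, Pon1 and Cyp1b1 kept theirs in all 8 and under 11 other alternatives. Mt1 passed without labelled knockout 2 (adjusted p = 0.029), and over its alternatives the adjusted p ran from 0.004 to 0.239. Exons of Ucp2, Mt2 and Vcam1 overlap a gene on the opposite strand.

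Partners of Klb in FGF21 signalling were looked at beside its fall by 1.14 on the log2 scale, and no difference between these genes was tested. The receptor gene Fgfr1 stood at 71.2 ± 7.98 against 70.4 ± 4.40 CPM, and Fgf21 itself was at 4.24 ± 1.74 against 2.10 ± 1.39 CPM (log2 fold change 1.04 ± 0.44, adjusted p = 0.296). The potassium channel gene Kcnh6 lay lower in all 4 libraries labelled knockout, at 4.09 ± 1.43 against 11.3 ± 3.79 CPM, with an adjusted p of 0.081, and from 0.000305 in DESeq2 to 0.208 over its alternatives.

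The first principal component held 36.0% of the variance and the second 17.8%. On the first, control 1 and control 4 lay at -42.1 and -27.2, controls 2 and 3 at 2.64 and -3.49, labelled knockout 4 at -2.45 and labelled knockouts 1 to 3 at 20.5, 29.4 and 22.6.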
